A study of Homo sapiens with 12 samples.

How the data were processed

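Polyadenylated RNA from 12 cultures or samples of human bone marrow cells, 3 in each of 4 groups, was sequenced after 24 h with pembrolizumab, nivolumab or the vehicle of either antibody. Per the labels, RNA was purified on silica columns (RNeasy) and libraries were made with a stranded mRNA kit (TruSeq). The submitters' processing notes name the genome build hg38; the aligner, the counting tool and their versions are not given in the sources used here. The authors deposited 1 file per library with 153438 RefSeq transcripts under 38654 gene names. Per the file headers, each file holds raw counts of reads per transcript, in a column of total reads and a column of reads unique to 1 transcript. The authors also gave TPM values, which sum to 1000000 per library. The deposited RPKM values are scaled to a library total that exceeds the sum of transcript reads, so that 6.21% to 7.84% of reads lie outside the transcripts. Reads unique to 1 transcript were 24.2% of the total in the median library. The files hold no protein-coding genes of the mitochondrial genome.

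Total reads of all transcripts of a gene were summed to gene counts, from 39727986 to 77868107 per library. Genes with too few reads for the group size were removed with filterByExpr, which left 16526, and libraries were scaled by TMM, with factors from 0.97 to 1.04. CPM values use these scaled totals; the levels of cell type markers and the limits for a count of 0, taken as 3 reads, use CPM of the unscaled totals. All 12 libraries were fitted in edgeR 4.0.16 with 4 group means and the robust quasi-likelihood F-test, so that the groups share an estimate of the spread (8 residual degrees of freedom, common biological coefficient of variation 0.0718). The tests, all two-sided, were pembrolizumab against its vehicle, nivolumab against its vehicle, the difference of these effects, and the vehicle group of the nivolumab experiment against that of the pembrolizumab experiment. P-values were adjusted by Benjamini-Hochberg over the genes of each test, and 0.05 was the threshold. An SE of a log2 fold change is the change divided by the square root of its F statistic.

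A set of 49 gene lists covering metabolism, cell cycle, stress, matrix, immune signalling and cell type markers held 834 symbols, of which 785 were found under the same name, 33 under an older name and 16 not at all. The 41 lists with at least 5 measured genes were tested with camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, with camera and an estimated correlation, and with fry; p-values were adjusted over the 41 lists. For each list, the genes were also adjusted over the list alone. Camera compares a list with the other genes, while fry tests whether its genes move on balance in 1 direction.

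The comparisons, the tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined, except where stated. In each antibody comparison the rule took up to 10 rising and 10 falling genes with the largest log2 fold change among those past the threshold, with a mean log2 CPM of at least 1, no overlap between the groups and a named symbol. It also took up to 4 members past the threshold of each called list, or the 2 with the smallest p if none had passed, and PDCD1, CD274 and PDCD1LG2; in the other comparisons it took up to 4 genes in each direction. The remaining called genes are listed as well. The Y chromosome and XIST were left out of every printed table, 206 genes in all.

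Alternatives were DESeq2 1.42.0; RLE and upper-quartile scaling; no filter, or at least 5 CPM in 3 libraries; limma on log2(TPM + 1) and log2(TPM + 0.1); unique reads; a test against a fold of 1.2; a replicate block; a fit of 6 libraries; all vehicle libraries as controls; and each library left out in turn. Added after the data were seen were thinning to the shallowest library, removal of each library's trend with GC content and transcript length (GC content known for 86.5% of genes), and the vehicle libraries of the other experiment as controls. Other splits of the samples were counted.

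The tests were tried on simulated data with changed genes planted in 3 against 3 libraries. For the pembrolizumab experiment edgeR recovered 58% of genes changed 1.25-fold, 86% at 1.5-fold and 100% at 2-fold, and 7.57% of its calls were false; for the nivolumab experiment these were 64%, 84%, 98% and 4.42%. False calls of DESeq2 were 15.5% and 10.6%. These shares belong to the simulated setting, with 50 genes planted at each fold from 1.25 to 3, all with a mean log2 CPM of at least 1. Many planted genes loosen the cutoff that the adjusted p sets. With as few calls as in the real libraries, a smaller share of changed genes may be recovered. For the set tests 1 list raised 1.1-fold was recovered by each method and 0 unchanged lists were called, but genes were simulated as independent, so these figures do not carry over to the real libraries, where other splits of the samples called up to 12 lists in the pembrolizumab experiment and 16 in the nivolumab experiment. No libraries were duplicates: log2 CPM correlated at 0.987 to 0.994 within groups. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used.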

Results

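Human bone marrow cells, listed in the labels as fibroblasts, were exposed for 24 h to pembrolizumab, to nivolumab or to the vehicle of either antibody, and their polyadenylated RNA was sequenced. Pembrolizumab and nivolumab are antibodies that block PD-1, an inhibitory receptor best known from T cells. The series addresses how checkpoint inhibitors act on the transcripts and the metabolism of cells that surround kidney tumours. The 12 libraries form 4 groups of 3: vehicle for pembrolizumab, pembrolizumab, vehicle for nivolumab, and nivolumab. An antibody and its own vehicle are called an experiment. The labels give no dose. They also do not say whether replicates are separate cultures or donors, so the p-values measure only the spread between these samples, which may be technical.

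Reads assigned to transcripts numbered 58123312, 54093250 and 60858592 in the vehicle libraries of the pembrolizumab experiment and 43810776, 42935398 and 39727986 in the pembrolizumab libraries. The vehicle libraries of the nivolumab experiment held 66569203, 77868107 and 68838900 and the nivolumab libraries 72313331, 68615902 and 66523733. FN1, which encodes the matrix protein fibronectin, was the most abundant gene in each library. On the first principal component, with 15.6% of the variance, the 3 pembrolizumab libraries lay at 23.2 to 33.0 and the highest of the other 9 libraries at 2.49.

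Transcripts of the fibroblast lineage dominated. COL1A2 and COL1A1, the chains of type I collagen, averaged 6868 and 6125 CPM (counts per 1000000 reads) over the 12 libraries, and the filament protein gene VIM averaged 2883 CPM. Genes typical of blood cells were low: the monocyte marker CD14 averaged 0.14 CPM and CSF1R 1.16 CPM, while CD68, a lysosomal protein found in many cells, reached 19.5 CPM. CD4 averaged 0.26 CPM, the cytotoxic granule gene GZMB 0.15 CPM, the neutrophil genes LTF 2.46 CPM and MPO 0.02 CPM, the progenitor gene GATA2 7.56 CPM and the haemoglobin gene HBA1 0.21 CPM. The plasma cell genes SDC1 and JCHAIN averaged 172 and 10.5 CPM, the transferrin receptor TFRC 686 CPM and the integrin ITGB3 75.0 CPM. The endothelial genes TEK and PECAM1 averaged 23.7 and 1.30 CPM, and the keratins KRT18 and KRT7 394 and 27.3 CPM. Of the marker lists of other cell types, 3 had the 5 measured genes needed for a test, and none of the 3 was called with either antibody (camera adjusted p from 0.19 to 0.76). Single markers, singled out after their values were seen, were lower with pembrolizumab without passing the threshold over all genes: JCHAIN had a log2 fold change of -0.52 and an adjusted p = 0.098, and PECAM1 -0.88 and an adjusted p = 0.12.

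The target of both antibodies was hardly transcribed. PDCD1, which encodes PD-1 (chromosome 2, 241849881 to 241858908, hg38), had 2 reads in all 12 libraries together, both in vehicle replicate 2 of the pembrolizumab experiment. A count of 0 allows up to 3 reads, or 0.0385 to 0.0755 CPM depending on the library, a limit that covers counting error only. Transcripts of its ligands were present. CD274, which encodes PD-L1 (chromosome 9, 5450503 to 5470567), had 308 to 576 reads per library, and PDCD1LG2, which encodes PD-L2, 510 to 929. CD274 stood at 6.57 ± 0.55 CPM with vehicle and 8.10 ± 0.92 CPM with pembrolizumab (mean ± SD, n = 3), a log2 fold change of 0.30 with an SE of 0.11 and an edgeR adjusted p = 0.22. It stood at 5.81 ± 0.30 CPM with vehicle and 7.66 ± 0.90 CPM with nivolumab, a log2 fold change of 0.40 with an SE of 0.11 and an adjusted p = 0.25. In each experiment the 3 antibody libraries lay above the 3 vehicle libraries, which chance alone gives, in either direction, for 10% of genes. PDCD1LG2 had log2 fold changes of 0.17 with pembrolizumab and 0.21 with nivolumab, with adjusted p = 0.50 and 0.63. The PDCD1LG2 value with nivolumab was -0.01 when only reads unique to 1 transcript were counted.

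Pembrolizumab was compared with its own vehicle to find what this antibody changed. IFITM1, an interferon-induced membrane protein that restricts viruses (chromosome 11, 313991 to 315272), fell from 12.8 ± 1.99 to 8.0 ± 0.56 CPM (mean ± SD, n = 3), a log2 fold change of -0.68 with an SE of 0.11. CMKLR1, the receptor for the chemoattractant chemerin (chromosome 12, 108288044 to 108339348), fell from 6.15 ± 1.31 to 3.01 ± 0.39 CPM, a log2 fold change of -1.03 with an SE of 0.18. JUNB, a subunit of the AP-1 transcription factor (chromosome 19, 12791496 to 12793311), fell from 51.3 ± 6.29 to 38.0 ± 1.15 CPM, and CSF1, the growth factor of macrophages (chromosome 1, 109910506 to 109930994), from 81.5 ± 2.33 to 66.3 ± 4.41 CPM. ITGA6, the integrin alpha-6 chain of laminin receptors (chromosome 2, 172427354 to 172506455), rose from 63.7 ± 4.42 to 83.3 ± 9.55 CPM, a log2 fold change of 0.39 with an SE of 0.07. HHIP, an inhibitor of hedgehog signalling, rose by a log2 fold change of 0.36.

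Of 16526 genes tested with edgeR, 24 passed an adjusted p of 0.05 with pembrolizumab: 5 rose and 19 fell. Besides ITGA6 and HHIP, the genes that rose were GNG11 (log2 fold change 0.34), SBDS (0.26), which encodes a ribosome maturation factor, and FEZ2 (0.25). CXXC5 had an adjusted p = 0.015 with a log2 fold change of -0.41, CLU, which encodes the secreted chaperone clusterin, 0.015 with -0.38, and the heparin-binding growth factor MDK 0.039 with -0.40. Also among those that fell were LURAP1L (-0.48), the stress-induced regulator NUPR1 (-0.46), ADGRB2 (-0.46), SSBP2 (-0.44), OLFML2B (-0.38), TNS2 (-0.38), CTSA (-0.29), ZFP36L1 (-0.27) and ADD3 (-0.25). The autophagy kinase ULK1 fell as well (-0.25), but its value was 0.16 with reads unique to 1 transcript. Only CMKLR1, APOL3 (-1.32) and PPL (-1.25) changed by more than 2-fold; APOL3 averaged 1.85 CPM and PPL 2.53 CPM with vehicle. An unadjusted p under 0.05 was found for 2329 genes where 826.3 would be so by chance, and the groups did not overlap for 15.8% of genes where chance gives 10%. The 3 pembrolizumab libraries were the shallowest of the 12; with all libraries thinned to the shallowest total 26 genes were called, 19 of them among the 24. The count of 24 rests on single libraries: it was 0 without vehicle replicate 1, 294 without vehicle replicate 2, 0 without vehicle replicate 3, and 67, 2 and 8 without pembrolizumab replicates 1, 2 and 3. It was 411 with DESeq2, 12 with limma on log2(TPM + 1), 8 with RLE scaling (0 higher and 8 lower), 333 without a filter on low counts, 242 with a replicate block, 849 against all 6 vehicle libraries, 4 with reads unique to 1 transcript, 5 with GC content and length trends removed, and 0 in a fit of these 6 libraries alone or against a fold of 1.2. The balance of directions varied as well: 179 were higher and 232 lower with DESeq2, 97 and 236 without a filter, 75 and 167 with a replicate block, 142 and 152 without vehicle replicate 2, 448 and 401 against all 6 vehicle libraries, and 1109 and 1220 at an unadjusted p under 0.05 in edgeR.

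**Figure D1:**
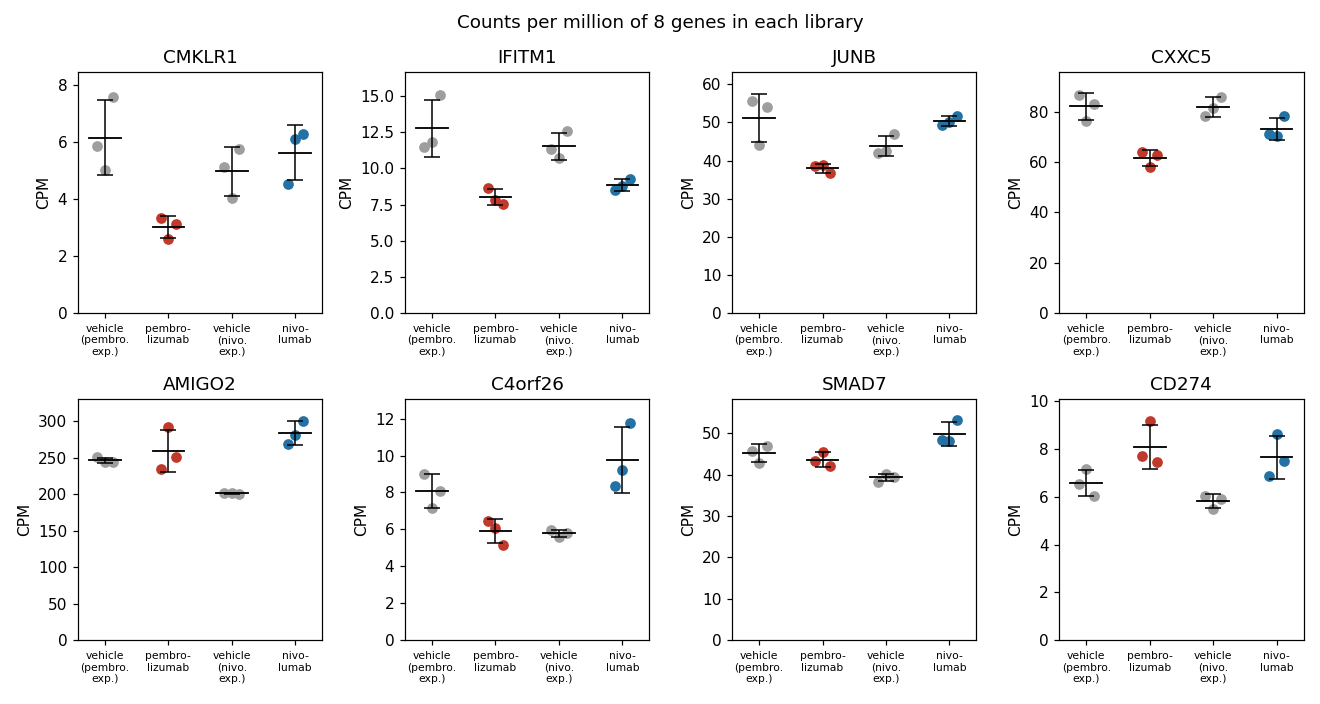
CPM (counts per 1000000 reads, vertical axis) of 8 genes in each of the 12 libraries. Points are libraries, horizontal lines are group means and bars are SDs with n = 3; CMKLR1, IFITM1, JUNB and CXXC5 were called with pembrolizumab, AMIGO2, C4orf26 and SMAD7 with nivolumab, and CD274 with neither, and CMKLR1 averaged 6.15 CPM with vehicle and 3.01 CPM with pembrolizumab.

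Among the gene lists, genes of G2 and mitosis were higher with pembrolizumab. All 24 measured members had a positive log2 fold change, with a median of 0.16. When p was adjusted over the list alone 15 rose, and over all genes 0 did (camera adjusted p = 1.8e-13; adjusted p = 0.47 with an estimated correlation). The spindle checkpoint kinase BUB1 had a log2 fold change of 0.19 with an SE of 0.05, and the mitotic kinase AURKA 0.24 with an SE of 0.07. The list of S phase and replication was not called, with a median of -0.09 and an adjusted p = 0.074. The heat shock list was higher with a median of 0.05, and 10 of its 13 measured members were positive (camera adjusted p = 0.012; adjusted p = 0.47 with an estimated correlation). Adjusted over the list alone 2 of its members rose, and over all genes 0. The chaperone HSP90AA1 had a log2 fold change of 0.27 (adjusted p = 0.062), although -0.07 with reads unique to 1 transcript, and HSPH1 had 0.19. The list of MYC targets and ribosome biogenesis was higher with a median of 0.04, 13 of 21 members positive (camera adjusted p = 0.012; adjusted p = 0.47 with an estimated correlation). Adjusted over the list alone 1 of its members rose, and over all genes 0. ODC1, the rate-limiting enzyme of polyamine synthesis, had a log2 fold change of 0.34 (adjusted p = 0.052), and NOP58 0.16. The heat shock call ended without pembrolizumab replicate 1 (adjusted p = 0.071) or vehicle replicate 3 (0.092), and the MYC call without pembrolizumab replicate 2 (0.23) or vehicle replicate 1 (0.085).

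Matrix genes were lower with pembrolizumab. Of 18 collagens, 15 had a negative log2 fold change, with a median of -0.15 (camera adjusted p = 0.00070; adjusted p = 0.47 with an estimated correlation), and adjusted over the list alone or over all genes 0 fell. With GC content and length trends removed the median was -0.06. COL3A1, the chain of type III collagen, stood at 2419.6 ± 82.0 CPM with vehicle and 1700.2 ± 341 CPM with pembrolizumab, a log2 fold change of -0.51 with an SE of 0.15 and an adjusted p = 0.18, and COL11A1 had a log2 fold change of -0.56. Of 21 matrix glycoproteins and proteoglycans, 16 were negative, with a median of -0.15 (camera adjusted p = 0.00044; adjusted p = 0.47 with an estimated correlation). Adjusted over the list alone 5 fell, and over all genes 0; FBLN1 had a log2 fold change of -0.21 and the crosslinking enzyme LOXL1 -0.27. Metalloproteinases and their inhibitors had a median of -0.16, with 11 of 15 negative (camera adjusted p = 0.015; adjusted p = 0.47 with an estimated correlation). Adjusted over the list alone 3 of them fell and 1 rose, and over all genes 0 passed; TIMP3 had a log2 fold change of -0.39 and MMP2 -0.25. Between the vehicle groups this last list also differed, with a median of -0.12 for the vehicle of the nivolumab experiment against that of this experiment, so the vehicle libraries compared here were the higher ones. The metalloproteinase call ended without pembrolizumab replicate 3 (adjusted p = 0.31), without vehicle replicate 3 (0.11) or with a strict filter on low counts (0.059).

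Stress, interferon and signalling lists were also lower with pembrolizumab. The integrated stress response, driven by the transcription factor ATF4, had a median of -0.26 with 12 of 15 members negative (camera adjusted p = 0.0011; adjusted p = 0.47 with an estimated correlation). With p adjusted over the list alone 6 fell and 1 rose, and over all genes only NUPR1 fell. The type I interferon list had a median of -0.17 with 18 of 25 negative, and IFITM1 was the member that fell, both over the list alone and over all genes (camera adjusted p = 0.012; adjusted p = 0.47 with an estimated correlation). The interferon gamma and MHC class I list had a median of -0.10 with 19 of 22 negative (camera adjusted p = 0.00066; adjusted p = 0.47 with an estimated correlation). With p adjusted over the list alone 2 of its members fell, and over all genes 0; the transcription factor IRF1 had a log2 fold change of -0.36 (adjusted p = 0.067) and the immunoproteasome subunit PSMB8 -0.28. Bone marrow niche factors had a median of -0.08 with 12 of 18 negative, of which 3 fell over the list alone and only CSF1 over all genes (camera adjusted p = 0.013; adjusted p = 0.36 with an estimated correlation). The p53 targets had a median of -0.05 with 13 of 18 negative, of which 3 fell over the list alone and 0 over all genes (camera adjusted p = 0.012; adjusted p = 0.36 with an estimated correlation). BTG2 had a log2 fold change of -0.90 and the cell cycle inhibitor CDKN1A -0.21. Immediate early genes had a median of -0.07 with 15 of 22 negative, of which 4 fell and 1 rose over the list alone and only JUNB fell over all genes (camera adjusted p = 0.013; adjusted p = 0.47 with an estimated correlation). The vehicle libraries of this experiment were themselves higher in this list than those of the nivolumab experiment, with a median of -0.11 for the latter against the former, larger than the median with pembrolizumab. The type I interferon call ended without pembrolizumab replicate 2 (adjusted p = 0.23) or vehicle replicate 3 (0.11), and the immediate early call without pembrolizumab replicate 3 (0.35) or vehicle replicate 1 (0.060). A strict filter on low counts ended the calls of the immediate early genes (0.055) and the p53 targets (0.20).

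Among metabolic lists, cholesterol synthesis was lower with pembrolizumab, with a median of -0.07 and 20 of 25 members negative (camera adjusted p = 0.0068; adjusted p = 0.47 with an estimated correlation). With p adjusted over the list alone 1 of its members fell, and over all genes 0. TM7SF2, a sterol reductase, had a log2 fold change of -1.01 at 1.32 CPM with vehicle (adjusted p = 0.073), and SREBF2, the transcription factor of the pathway, -0.20, although 0.30 with reads unique to 1 transcript. The call ended without pembrolizumab replicate 2 (adjusted p = 0.064). Nuclear-encoded oxidative phosphorylation had a median of 0.04 (adjusted p = 0.056), glycolysis -0.06 (0.067) and the TCA cycle 0.0037 (0.43), and none of these was called. In all, 13 of the 41 lists tested were called, 3 higher and 10 lower; with an estimated correlation 0 were, and fry called the niche factors and the p53 targets, each with an adjusted p = 0.041. The count of lists was 20 without vehicle replicate 3 of the pembrolizumab experiment.

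The comparison of nivolumab with its own vehicle gave fewer genes in the fit of all 12 libraries. The order depended on the setting: in fits of 6 libraries nivolumab had 188 genes and pembrolizumab 0. AMIGO2, an adhesion protein (chromosome 12, 47075707 to 47080826), rose from 201 ± 0.42 to 283 ± 16.4 CPM (mean ± SD, n = 3), a log2 fold change of 0.50 with an SE of 0.06. SMAD7, an inhibitor of TGF-beta signalling that TGF-beta itself induces (chromosome 18, 48919853 to 48950711), rose from 39.3 ± 0.93 to 49.9 ± 2.87 CPM, a log2 fold change of 0.34 with an SE of 0.05. C4orf26, whose product is an acidic protein of tooth enamel (chromosome 4, 75554997 to 75565893), rose from 5.81 ± 0.19 to 9.77 ± 1.78 CPM, a log2 fold change of 0.75 with an SE of 0.12. PLPP3, a phosphatase that degrades lysophosphatidic acid (chromosome 1, 56494747 to 56579584), fell from 135 ± 3.77 to 101 ± 5.52 CPM, a log2 fold change of -0.42 with an SE of 0.06. EVI2A (chromosome 17, 31316410 to 31321749) fell from 12.4 ± 0.25 to 8.56 ± 0.58 CPM, a log2 fold change of -0.54 with an SE of 0.08.

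These 5 genes, 3 that rose and 2 that fell, are all that passed with nivolumab among 16526. Their adjusted p was 0.0074 for AMIGO2 and PLPP3, 0.027 for SMAD7 and EVI2A and 0.039 for C4orf26, and none changed by 2-fold. HBEGF (log2 fold change 0.37, adjusted p = 0.054) and CTGF (0.42, adjusted p = 0.062) missed the threshold; both were singled out after their values were seen. An unadjusted p under 0.05 was found for 1326 genes where 826.3 would be so by chance, and the groups did not overlap for 18.5% of genes where chance gives 10%. The count was 2, 0 and 2 without vehicle replicates 1, 2 and 3, and 0 without nivolumab replicate 2 or replicate 3. It was 117 with DESeq2, 0 with limma on log2(TPM + 1), 115 without a filter on low counts, 9 with a strict filter, 113 with a replicate block, 188 in a fit of these 6 libraries alone, 2 with reads unique to 1 transcript, 2 against all 6 vehicle libraries and 0 against a fold of 1.2; upper-quartile scaling gave 7, of which 5 rose and 2 fell. Against the vehicle libraries of the other experiment 7 genes were called, 0 of them among these 5; AMIGO2, for example, had 247 CPM in those vehicle libraries.

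**Figure D2:**
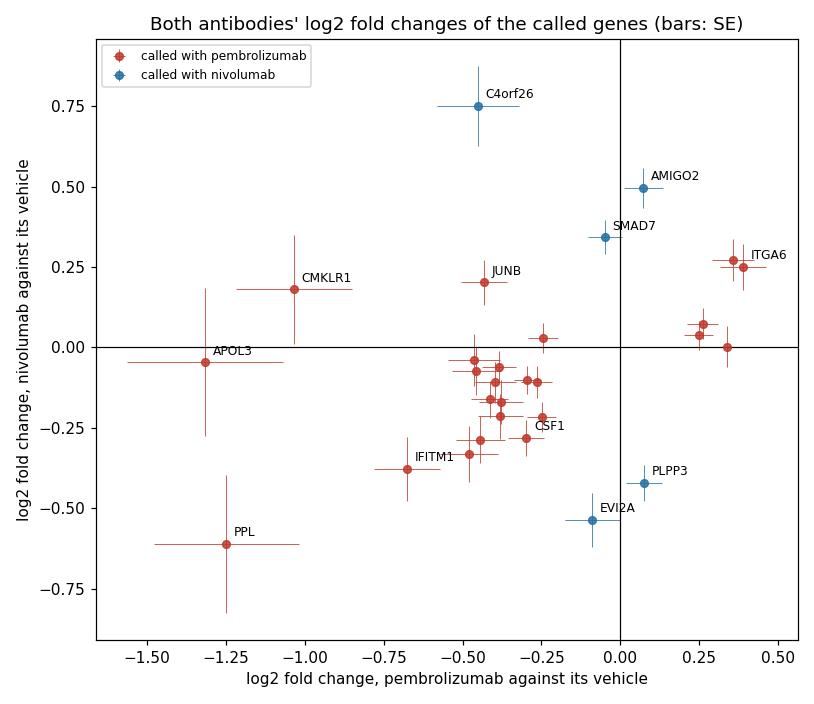
Log2 fold changes with pembrolizumab (horizontal axis) and with nivolumab (vertical axis), each against its own vehicle, of the 24 genes called with pembrolizumab (red) and the 5 called with nivolumab (blue). Bars are SEs; 21 of the 24 red genes have the same sign on both axes, and 2 of the 5 blue ones.

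The TGF-beta response and myofibroblast list was higher with nivolumab. Of its 19 members 17 were positive, with a median of 0.18; 7 rose over the list alone and only SMAD7 over all genes (camera adjusted p = 8.9e-11; adjusted p = 0.52 with an estimated correlation). The TGF-beta target CTGF, a member of this list, had a log2 fold change of 0.42. Between the vehicle groups the list was not called (median 0.0041, camera adjusted p = 0.26), but 3 of its members were lower over the list alone in the vehicle of this experiment. SMAD7 averaged 39.3 CPM there against 45.1 CPM in the vehicle of the pembrolizumab experiment, and CTGF 1611.5 against 1928.9 CPM. Collagens were higher, 16 of 18 positive with a median of 0.12 (camera adjusted p = 0.0028; adjusted p = 0.52 with an estimated correlation). With p adjusted over the list alone 1 collagen rose, and over all genes 0; COL6A3 had a log2 fold change of 0.27 and COL4A2 0.26. Matrix glycoproteins and proteoglycans had a median of 0.10 with 14 of 21 positive (camera adjusted p = 0.047; adjusted p = 0.56 with an estimated correlation), and metalloproteinases and inhibitors 0.04 with 11 of 15 positive (camera adjusted p = 0.044; adjusted p = 0.52 with an estimated correlation). With p adjusted over the list alone 0 of the former and 2 of the latter rose, and over all genes 0; VCAN had a log2 fold change of 0.26, TNC 0.23 and SERPINE2 0.33. For metalloproteinases and inhibitors the vehicle group of this experiment was itself lower than that of the pembrolizumab experiment, with a median of -0.12, larger than the median with nivolumab and opposite in sign. YAP and SRF targets had a median of 0.06 with 13 of 16 positive (camera adjusted p = 0.0055; adjusted p = 0.52 with an estimated correlation), of which 2 rose over the list alone and 0 over all genes; CTGF and CYR61 (0.18) belong to this list and to the TGF-beta list. The TGF-beta call held without each library. With GC content and length trends removed the collagen median was 0.07. The collagen call ended without vehicle replicate 2 (median 0.01, adjusted p = 0.40) or nivolumab replicate 2 (median 0.09, adjusted p = 0.056), and the YAP and SRF call without nivolumab replicate 3 (adjusted p = 0.23). The glycoprotein call ended without vehicle replicate 1 (adjusted p = 0.064), vehicle replicate 2 (median -0.02, adjusted p = 0.87), nivolumab replicate 2 (0.22), nivolumab replicate 3 (0.051) or with a strict filter (0.053). The metalloproteinase call ended without vehicle replicate 1 (0.21), vehicle replicate 2 (0.21), nivolumab replicate 1 (0.055) or nivolumab replicate 2 (0.14), and with a strict filter (0.053) or a replicate block (0.079).

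Immediate early genes were higher with nivolumab, with a median of 0.09 and 15 of 22 positive (camera adjusted p = 0.0041; adjusted p = 0.52 with an estimated correlation). Counted with p adjusted over the list alone 5 rose and 1 fell, and over all genes 0; IER2 had a log2 fold change of 0.26 and IER3 0.22. The list of NF-kappaB and inflammatory cytokines had a median of 0.13 with 19 of 27 positive (camera adjusted p = 0.0055; adjusted p = 0.52 with an estimated correlation), of which 1 rose over the list alone and 0 over all genes. Its cytokines IL11 and LIF had log2 fold changes of 0.56 and 0.36. The vehicle libraries of this experiment were themselves lower than those of the pembrolizumab experiment in both lists, with medians of -0.11 for immediate early genes and -0.24 for NF-kappaB, at least as large as the medians with nivolumab and opposite in sign. Checkpoint ligands and receptors had a median of 0.12 with 11 of 14 positive, of which 1 rose over the list alone and 0 over all genes (camera adjusted p = 0.047; adjusted p = 0.52 with an estimated correlation); CD274 had 0.40 and NT5E, an enzyme that makes adenosine, 0.31. The unfolded protein response had a median of 0.04 with 15 of 18 positive, and 0 rose over the list alone or over all genes (camera adjusted p = 0.017; adjusted p = 0.52 with an estimated correlation); EDEM1 had 0.13, and DNAJC3 0.09, although -0.52 with reads unique to 1 transcript. The immediate early call ended without vehicle replicate 1 (adjusted p = 0.052), and the NF-kappaB call without vehicle replicate 2 (0.084) or nivolumab replicate 2 (0.052). The checkpoint call ended without vehicle replicate 1 (0.11), vehicle replicate 2 (0.19) or nivolumab replicate 2 (0.18), in the fit of 6 libraries (0.087) and with a replicate block (0.061). The unfolded protein call ended without vehicle replicate 1 (0.052), vehicle replicate 2 (median -0.01, adjusted p = 0.51) or nivolumab replicate 2 (0.14).

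Translation, replication, energy and interferon lists were lower with nivolumab. Of 48 ribosomal protein genes 45 were negative, with a median of -0.06, and 0 fell over the list alone or over all genes (camera adjusted p = 4.6e-05; adjusted p = 0.52 with an estimated correlation); RPS24 had a log2 fold change of -0.14 and RPS4X -0.11. Genes of S phase and replication had a median of -0.07 with 19 of 24 negative, and 0 fell over the list alone or over all genes (camera adjusted p = 0.0028; adjusted p = 0.52 with an estimated correlation); the helicase subunits MCM3 and MCM4 had -0.15 and -0.13. Nuclear-encoded oxidative phosphorylation had a median of -0.04 with 34 of 43 negative (camera adjusted p = 0.031; adjusted p = 0.53 with an estimated correlation), and glycolysis -0.05 with 16 of 20 negative (camera adjusted p = 0.040; adjusted p = 0.56 with an estimated correlation). In both lists 0 fell over the list alone or over all genes; UQCRB had -0.15, LDHA, the enzyme that makes lactate, -0.19, PFKFB4 -0.31, although 0.96 with reads unique to 1 transcript, and COX5B -0.11, although 0.02 against the other experiment's vehicle. Glycolysis was higher in the vehicle libraries of this experiment than in those of the pembrolizumab experiment, with a median of 0.09, larger than the median with nivolumab and opposite in sign. Ribosomal proteins and oxidative phosphorylation were each higher there too, with medians of 0.03, smaller than those with nivolumab. The type I interferon list had a median of -0.09 with 18 of 25 negative, of which 1 fell over the list alone and 0 over all genes (camera adjusted p = 0.040; adjusted p = 0.52 with an estimated correlation); IFITM1 had -0.38. The interferon gamma list had a median of -0.05 with 16 of 22 negative, and 0 fell over the list alone or over all genes (camera adjusted p = 0.040; adjusted p = 0.52 with an estimated correlation); PSMB8 had -0.26 and GBP2 -0.50. The S phase call held without each library. Without vehicle replicate 3 the calls ended of the ribosomal proteins (adjusted p = 0.17), oxidative phosphorylation (0.77), glycolysis (0.89) and the interferon gamma list (0.38). Oxidative phosphorylation also lost its call without nivolumab replicate 3 (0.19), glycolysis without nivolumab replicates 1 (0.16) or 2 (0.074), the interferon gamma list without nivolumab replicates 1 (0.16) or 2 (0.052) or with a strict filter (0.089), and the type I list without vehicle replicate 2 (0.15), nivolumab replicates 1 (0.057) or 2 (0.074) or with a strict filter (0.062).

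In all, 15 of the 41 lists were called with nivolumab, 9 higher and 6 lower; with an estimated correlation or with fry 0 were. Without nivolumab replicate 2 the count was 6.

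**Figure D3:**
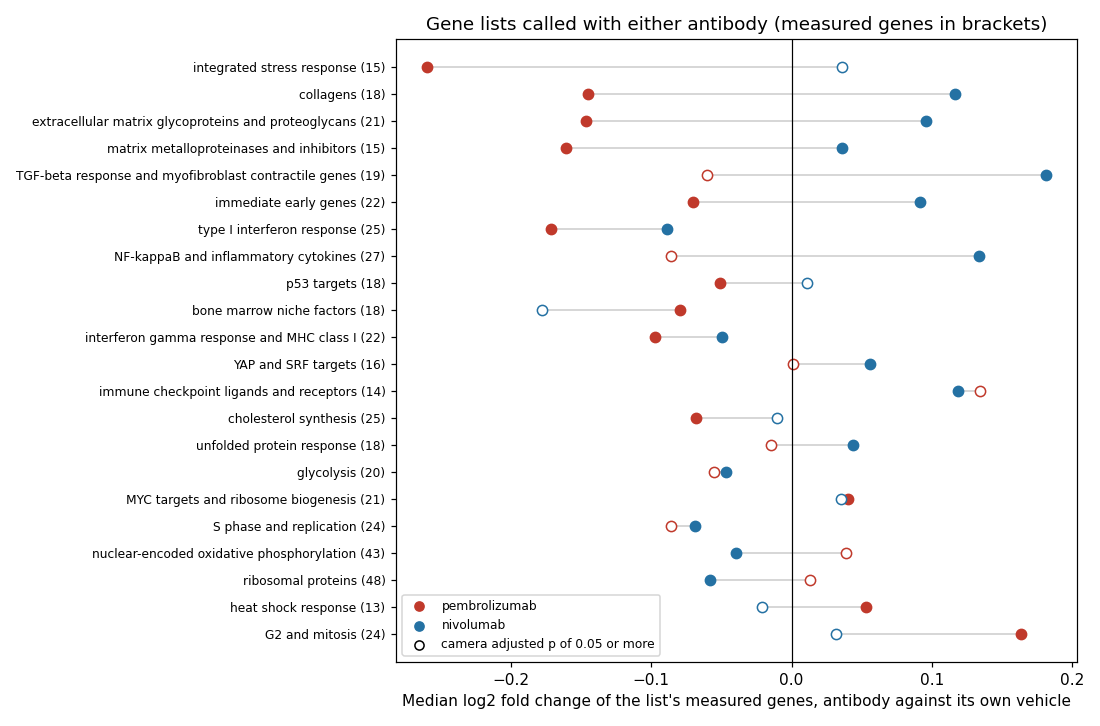
Median log2 fold change (horizontal axis) of each gene list called with either antibody, with the number of measured genes in brackets. Red is pembrolizumab and blue nivolumab, each against its own vehicle, and open circles have a camera adjusted p of 0.05 or more; the collagen medians are -0.15 with pembrolizumab and 0.12 with nivolumab.

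Whether the antibodies differed was tested as the nivolumab effect minus the pembrolizumab effect. C4orf26 had a log2 difference of 1.2 with an SE of 0.18 and an adjusted p = 0.055, JUNB 0.63 with an SE of 0.10 and an adjusted p = 0.057, and PLPP3 -0.50 with an SE of 0.08 and an adjusted p = 0.057; these were singled out after their values were seen. With edgeR 0 genes passed, against 1494 at an unadjusted p under 0.05; DESeq2 called 52 and limma on log2(TPM + 1) 0. The count was 35 without a filter on low counts, 10 with a replicate block, 6 without vehicle replicate 2 of the pembrolizumab experiment, 3 without pembrolizumab replicate 2 and 1 without nivolumab replicate 1. Collagens had a median difference of 0.29, 17 of 18 positive, and matrix glycoproteins and proteoglycans 0.23, 21 of 21 positive (camera adjusted p = 7.4e-08 and 3.0e-06; adjusted p = 0.41 for both with an estimated correlation). The TGF-beta list had 0.18 with 19 of 19 positive, and G2 and mitosis -0.14 with 23 of 24 negative (camera adjusted p = 7.4e-08 for both; adjusted p = 0.41 and 0.50 with an estimated correlation). Counted with p adjusted over the list alone 3 genes of the TGF-beta list, 1 of the glycoprotein list and 0 of the collagen and mitosis lists passed, and over all genes 0 did. In total 15 of 41 lists were called, 10 higher and 5 lower, and with an estimated correlation or with fry 0 were.

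The calls of the antibodies were also laid side by side. No gene was called with both, where independent lists would share close to 0 genes, but 21 of the 24 genes called with pembrolizumab had the same sign with nivolumab, among them IFITM1 (-0.38), and 2 of the 5 called with nivolumab had the same sign with pembrolizumab. The count of shared genes was 15 with DESeq2, 21 without a filter on low counts, 26 with a replicate block, 0 with limma on log2(TPM + 1) and 2 without vehicle replicate 2 of the pembrolizumab experiment. Across genes, which are not independent replicates, the log2 fold changes with the antibodies had a Pearson r of -0.02 and a Spearman rho of 0.10.

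The vehicle groups were compared as a background. The labels name a vehicle for each antibody, so the groups may differ by vehicle solution as well as by experiment. SNORA104, a small nucleolar RNA (chromosome 19, 14622213 to 14622351), stood at 5.86 ± 0.24 CPM in the vehicle libraries of the pembrolizumab experiment and 1.99 ± 0.14 CPM in those of the nivolumab experiment (mean ± SD, n = 3), a log2 fold change of -1.56 with an SE of 0.13. The readthrough gene RPL17-C18orf32 was lower by a log2 fold change of -0.59. In all 8 genes passed with edgeR, 1 higher and 7 lower in the nivolumab experiment. The others, named after their values were seen, were RPS26P11 (2.50), LOC105373943 (-5.65), SLC30A10 (-3.87), a mitochondrial tRNA gene (-3.01), MAP1LC3B2 (-1.62) and LOC107987279 (-1.58). The first 4 of these were low. LOC105373943 had 0.50 to 0.61 CPM in the vehicle libraries of the pembrolizumab experiment and 0 to 0.015 CPM in those of the nivolumab experiment. In the same order SLC30A10 had 0.97 to 1.43 and 0.05 to 0.12 CPM, the tRNA gene 0.40 to 1.21 and 0.06 to 0.11 CPM, and RPS26P11 0.13 to 0.45 and 1.63 to 2.10 CPM. EGR1, an immediate early gene also singled out after its values were seen, had a log2 fold change of -0.97 and an adjusted p = 0.061. An unadjusted p under 0.05 was found for 692 genes where 826.3 would be so by chance, and 9.85% of genes did not overlap where chance gives 10%. The list of NF-kappaB and inflammatory cytokines was lower in the vehicle libraries of the nivolumab experiment, with a median of -0.24, and so were the immediate early genes with -0.11 (camera adjusted p = 1.8e-05 and 4.4e-05; adjusted p = 0.47 for both with an estimated correlation). Counted with p adjusted over the list alone 1 of the former fell, and of the latter 5 fell and 1 rose; over all genes 0 did. Glycolysis was higher with a median of 0.09, 19 of 20 positive, with 0 members past the threshold over the list alone or over all genes (camera adjusted p = 6.1e-06; adjusted p = 0.75 with an estimated correlation). The epithelial and renal tumour markers were higher with a median of 0.13, 7 of 9 positive, with 0 members past the threshold over the list alone or over all genes (camera adjusted p = 0.017; adjusted p = 0.47 with an estimated correlation). Also called were metalloproteinases and inhibitors (median -0.12), MYC targets and ribosome biogenesis (-0.04), G2 and mitosis (-0.04), cholesterol synthesis (0.04), ribosomal proteins (0.03) and oxidative phosphorylation (0.03), with camera adjusted p from 0.0068 to 0.033, adjusted p from 0.75 to 0.94 with an estimated correlation and 0 members past the threshold over the list alone or over all genes. In all 10 lists were called, 5 higher and 5 lower, of which 0 were called with an estimated correlation or with fry. The gene count was 22 with DESeq2, 29 without a filter on low counts, 1 with a strict filter, 124 with reads unique to 1 transcript, 14 in a fit of the 6 vehicle libraries, 5 without vehicle replicate 2 of the pembrolizumab experiment, and 4, 3 and 5 without vehicle replicates 1, 2 and 3 of the nivolumab experiment.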

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

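Chosen only after the results were seen were the tests of each antibody's collagen call with single libraries left out, thinning and removal of GC content and length trends as alternatives, and the use of a spread over resampled genes to judge gaps on the principal component.

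The antibodies' effects on gene lists differed in 13 lists called with either antibody, by camera on the difference of the effects (nivolumab minus pembrolizumab), while with an estimated correlation 0 of them did. Median log2 differences were 0.29 for collagens, 0.23 for matrix glycoproteins and proteoglycans, 0.19 for metalloproteinases and inhibitors, 0.18 for the TGF-beta list, 0.18 for immediate early genes and 0.060 for YAP and SRF targets. They were 0.36 for the integrated stress response, 0.16 for NF-kappaB and inflammatory cytokines and 0.079 for p53 targets, and -0.14 for G2 and mitosis, -0.12 for heat shock, -0.068 for ribosomal proteins and -0.063 for oxidative phosphorylation. With adjusted p from 0.23 to 0.68 under an estimated correlation, these differences remain unsettled.

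Of the 75 genes named in the antibody comparisons, 5 had all libraries of one experiment on one side of their vehicle and all of the other on the opposite side. EGR1, named only between the vehicle groups, was not among the 75. Many of the 75 were picked for their change in 1 experiment, so some such cases arise by chance. Over all genes 204 were apart in opposite directions, where 241.1 would be if the experiments were independent. The 5 therefore do not show opposite responses by their number. JUNB had log2 fold changes of -0.43 with pembrolizumab and 0.20 with nivolumab, C4orf26 -0.45 and 0.75, LIF -0.27 and 0.36, RPS24 0.12 and -0.14, and UQCRB 0.10 and -0.15. The difference itself did not pass in edgeR, with adjusted p = 0.057 for JUNB, 0.055 for C4orf26, 0.45 for LIF, 0.35 for RPS24 and 0.42 for UQCRB. For all 5 the mean CPM of the vehicle groups also differed, in the direction that makes the effects opposite. JUNB, for example, averaged 51.3 CPM with the vehicle of the pembrolizumab experiment and 43.8 CPM with that of the nivolumab experiment. How much this offset adds to the opposite signs was not tested.

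The first pattern is that the pembrolizumab libraries stood apart from the other 9 on the first principal component, with a gap of 20.7 and an SD of 4.78 over 100 resamplings of the genes. The nearest of the 9 was vehicle replicate 2 of the same experiment, so the gap is one to the antibody's own vehicle libraries. Lower depth stays open, since with all libraries thinned to the shallowest the gap was 9.45, below the bound of 10 set before. It ranged from 7.42 to 11.98 over 20 thinnings, but its SD over resampled genes was 10.07, larger than the gap itself. A trend with GC content and length also stays open. Its removal took the gap for the same genes from 16.5 to 10.97, above the bound of 10, which alone would argue against the trend. The gap exceeded that bound by less than its SD of 5.32, a criterion settled after the first gaps were seen. Only 3 of the 24 pembrolizumab calls remained. Over all 24 genes, which kept their direction, the median absolute log2 fold change was 0.32 in place of 0.39. Their median SE was 0.065 in place of 0.067. The refit also covered 14295 genes in place of 16526, and what ended the calls was not separated. Handling of these 3 libraries coincides with the antibody and cannot be told apart from it, and an effect of pembrolizumab is among the explanations that stay open.

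The second pattern is that collagens were lower with pembrolizumab and higher with nivolumab, a median difference of 0.29. A trend with GC content and length is argued against as the sole cause, since with the trends removed the difference was 0.18, above the bound of 0.1 set before, though the medians shrank from -0.15 to -0.06 and from 0.12 to 0.07. A single library is argued against for the difference, whose lowest value with 1 library left out was 0.21, and for the pembrolizumab part, whose median nearest to 0 was -0.088, without pembrolizumab replicate 2. For the nivolumab part it may be the cause: without vehicle replicate 2 the median was 0.015 and the call ended. The verdicts on single libraries for each antibody rest on camera calls with the preset correlation. A difference between the antibodies stays open as a biological explanation for the rest, and it was not separated from handling of the experiments. Chance differences between these samples stay open too. With an estimated correlation the camera adjusted p of the difference was 0.41, and 0 of 18 collagens passed over the list alone.

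The sample groupings were set against other splits. For pembrolizumab, nivolumab, the vehicle groups and both counts of lists, 10 splits are too few for a share under 0.05. The real count and the highest of the other splits were 24 and 81 for pembrolizumab, 5 and 1 for nivolumab, 8 and 0 for the vehicle groups, 13 and 12 for lists with pembrolizumab and 15 and 16 for lists with nivolumab. With the real split itself counted, 2, 1, 1, 1 and 4 of the 10 splits, in this order, gave at least the real count. The split with 81 genes set vehicle replicates 1 and 2 and pembrolizumab replicate 1 against the rest, several times the real count. A structure among these 6 libraries that the groups do not describe may underlie this, but it was not tested. For the difference between the antibodies the splits decide nothing, since with a real count of 0 all 100 of 100 splits give at least as many by construction. The highest other split, with 114 genes, exchanges antibody and vehicle in the nivolumab experiment and is thereby the mean effect of both antibodies.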

How the results depend on the processing

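Removal of GC content and length trends, thinning and the other experiment's vehicle as control were chosen only after the results were seen; the other alternatives were planned. The counts depend on the setting: under the alternatives and with single libraries left out, 58 counts moved by more than 1.5 times and 68 did not, and for pembrolizumab they ran from 0 to 849, while fold changes of named genes kept their direction in all but 7 cases. Most named genes were chosen for a small p or for groups without overlap in the main fit, which makes a reversal unlikely from the start. Unless stated, the cause of a change with the setting was not tested.

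With DESeq2 the counts were 411 for pembrolizumab (24 of them the main calls), 117 for nivolumab, 52 for the difference, 22 for the vehicle groups and 15 shared. With no filter on low counts they were 333, 115, 35, 29 and 21. RLE scaling gave 8 for pembrolizumab, 0 higher and 8 lower, and a strict filter 9 for nivolumab and 1 for the vehicle groups. The strict filter removes low genes, but both SNORA104 and RPL17-C18orf32 pass it. Removal of low genes alone therefore does not account for the count of the vehicle groups. A replicate block gave 242, 113, 10 for the difference and 26 shared. The replicate numbers are not stated to pair. Antibody and vehicle libraries were correlated after each group's mean was subtracted per gene. In the pembrolizumab experiment the correlations were 0.084 to 0.122 for the same number and -0.071 to -0.015 for different numbers. In the nivolumab experiment they were -0.050 to -0.021 and -0.019 to 0.066. Limma on log2(TPM + 1) or log2(TPM + 0.1) gave 12 for pembrolizumab and 0 for nivolumab, and reads unique to 1 transcript gave 4, 2 and 124 for the vehicle groups. Against a fold of 1.2 both antibodies had 0. In fits of 6 libraries pembrolizumab had 0, nivolumab 188 and the vehicle groups 14; these fits no longer share the spread over the 4 groups. All 6 vehicle libraries as controls gave 849 for pembrolizumab and 2 for nivolumab, the other experiment's vehicle 800 for pembrolizumab, and removal of GC content and length trends 5. Against the other experiment's vehicle 22 of the 24 main pembrolizumab calls stayed called and all 24 kept their direction, with the same pembrolizumab libraries. Of the 5 nivolumab calls 0 stayed called there. Lists called with an estimated correlation were 0 for both antibodies, and with fry 2 and 0.

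With 1 library left out, the counts ran from 0 to 294 for pembrolizumab, 0 to 4 for nivolumab, 0 to 6 for the difference, 3 to 8 for the vehicle groups and 0 to 2 shared, and list counts from 10 to 20 for pembrolizumab and 6 to 17 for nivolumab.

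The direction reversed with reads unique to 1 transcript, which were 0.169% to 4.89% of the reads of these genes and gave adjusted p from 0.86 to 0.999, for SREBF2 (0.30), HSP90AA1 (-0.075) and ULK1 (0.16) with pembrolizumab and for DNAJC3 (-0.52), PFKFB4 (0.96) and PDCD1LG2 (-0.0051) with nivolumab; with the other experiment's vehicle it reversed for COX5B with nivolumab (0.025). Called lists kept the set test's direction and their call in 201 cases, and kept the direction but lost the call in 107. That direction is not the sign of the median. With nivolumab the medians of matrix glycoproteins and of the unfolded protein response turned negative without vehicle replicate 2. At depths of 39727986 to 77868107 reads PDCD1 stayed below the filter.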

Other observations

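The mean effect of the antibodies and the direct contrast of the antibody groups were chosen only after the results were seen, and so were the test of the mean effect on other splits, whose criterion was set before that test was run, and the counts of genes apart in both experiments.

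The mean of the effects, each against its own vehicle, was tested for genes changed on average by the antibodies. All 114 called genes had the same sign in both experiments, but a call on the mean does not show a change with each antibody. AMIGO2, for example, had log2 fold changes of 0.07 with pembrolizumab and 0.50 with nivolumab, and CLU -0.38 and -0.06. No gene list was tested on this mean, so the genes below stand for themselves and not for a class. CSF1 fell by a mean log2 fold change of -0.29 with an SE of 0.04 (edgeR adjusted p = 0.0068; -0.30 with pembrolizumab and -0.28 with nivolumab). The antiviral membrane proteins IFITM1, IFITM2 and IFITM3, which lie together on chromosome 11, fell by -0.53, -0.26 and -0.29, the immunoproteasome subunit PSMB8 by -0.27 and the DNA sensor IFI16 by -0.22. The ligands TGFB2 (-0.20), TGFB3 (-0.43), BMP4 (-0.32) and FLT3LG (-0.64) fell, as did JCHAIN, a marker of plasma cells (-0.41, adjusted p = 0.040), RUNX2, the transcription factor of bone formation (-0.27), the lipogenic regulator SREBF1 (-0.28) and the TGF-beta-activating integrin ITGB8 (-0.35). Genes that rose included the growth factors HBEGF (0.32), GDNF (0.36) and PGF (0.30), the vasoconstrictor EDN1 (0.36), ESM1 (0.96), HHIP (0.31), ITGA6 (0.32) and ODC1 (0.27). CD274, which encodes the ligand of the antibodies' target, rose by 0.35 with an SE of 0.08 (adjusted p = 0.047). Of the 114 called genes 84 had no overlap between antibody and vehicle libraries in both experiments, which their selection on these same libraries favours. Among those named here AMIGO2, CLU, IFI16, TGFB3 and EDN1 did overlap in at least 1 experiment. These genes were picked from the called ones after their values were seen.

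In all 114 genes passed, 43 higher and 71 lower, and 2179 had an unadjusted p under 0.05. Among all genes, 360 had no overlap with the vehicle libraries in both experiments and moved the same way in both, where the share of such genes in each experiment would give 241.2 if the experiments were independent. In opposite directions 204 did, where 241.1 would. For 3 against 3 libraries chance alone separates 10% of genes in each experiment, and genes are not independent replicates. In 100 splits within the experiments only the real one called as many as 114 genes, 1 of 100, and the highest other called 57. That argues against a chance assignment of these libraries to groups as the sole source of the 114. The mean was chosen after the results were seen, however, so the share of splits is not a clean test. If the libraries of a group come from 1 culture, exchanging libraries also leaves chance differences between cultures untested. A shared response to both antibodies may underlie the 114 or part of them. A difference between antibody and vehicle solutions other than PD-1 binding would look the same as a shared response and was not tested. The 114 were also not recomputed with thinned libraries or with GC content and length trends removed. These trends explained 2.64% to 4.59% of the deviation from the gene means in nivolumab libraries and 0.58% to 1.73% in their vehicle libraries. In the pembrolizumab experiment they explained 0.97% to 7.1% with the antibody and 0.79% to 1.77% with vehicle. A trend shared by both antibodies thus stays open. Single genes were not recomputed with libraries left out. The number rests on single libraries: it was 8 and 11 without nivolumab replicates 1 and 2, and 21, 37 and 33 without vehicle replicates 1, 2 and 3 of that experiment. It was 14, 305 and 56 without vehicle replicates 1, 2 and 3 of the pembrolizumab experiment, and 30 and 241 without pembrolizumab replicates 2 and 3. With a replicate block it was 402, of which 113 were among the 114.

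The nivolumab and pembrolizumab libraries were also compared directly, without their vehicles. This gave 536 genes, 225 higher and 311 lower with nivolumab; 7 of the 8 genes that differed between the vehicle groups were among them, as were 16 of the 24 called with pembrolizumab and 3 of the 5 called with nivolumab. The contrast mixes the antibodies with the experiments.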
